A study of Rhizorhabdus wittichii with 9 samples.

How the data were processed

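RNA of Rhizorhabdus (Sphingomonas) wittichii RW1, a bacterium known for using dibenzo-p-dioxin as a carbon source, was sequenced from 9 liquid cultures in early to mid log phase. There were 3 biological replicates, per the series design text, for each of 3 sole carbon sources: succinate at 20 mM, crystalline dibenzo-p-dioxin at 365 µM, and clay-sorbed dibenzo-p-dioxin, for which 1% (w/v) loaded clay corresponded to the same 365 µM. The treatment protocol in the labels also speaks of clay without dioxin and of dioxin with clay added beside it, which were not analysed here. Cultures grew at 30 °C in a defined mineral medium. Total RNA was treated with DNase before library preparation, per the labels' protocols. How ribosomal RNA was handled, the strandedness of the libraries, the counting tool, the genome build and the annotation are not given in the sources used here. CASAVA 1.8 and Bowtie 1.0.0 are named in the submitters' processing notes, without their settings.

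The authors deposited a table of raw read counts per locus tag, with 1 column per library and 5398 tags, and a table of RPKM with 1 value per carbon source and tag. All tests used the deposited counts. The deposited RPKM values combine the replicates of a group, so they carry no error and entered no test. The tables share 5397 tags. The counts summed to between 256186 and 572426 per library, with a median of 9 to 22 counts per tag, and 34 tags had no count in any library. At this depth a tag with few counts is measured poorly, and intervals from counts cover counting error only. In simulated data built from the real means, spreads and library sizes, with 200 tags changed, the same procedure recovered 45.4% of 2-fold and 96.0% of 4-fold changes for crystalline dioxin against succinate among 3334 tags tested. For clay-sorbed dioxin against succinate it recovered 45.8% and 91.8% among 3305 tags, and for clay-sorbed against crystalline dioxin 44.9% and 93.5% among 3299 tags. Between 5.07% and 9.15% of its calls were false.

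The files do not pair the tags with gene names. The reference table in hand describes another strain, MPO218, and 0 of the 5398 tags matched it. Of 28 gene lists fixed before the data were examined, 27 were defined by product names and could not be filled. The remaining list, the dioxin upper pathway, held 8 locus tags with functions published for this strain. These functions were not checked against an annotation here, and no coordinates are given. Planned comparisons of replicons, of ribosomal and transfer RNA genes, and of RPKM per library were not possible for the same reasons. Reads shared between near-identical genes or antisense partners could not be examined without sequence.

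Counts were analysed in R 4.3.3 with edgeR 4.0.16. Tags were kept by filterByExpr (3499 tags), libraries were scaled by the trimmed mean of M values (TMM), and all 9 libraries entered 1 quasi-likelihood fit with a mean per group. Each of the 3 comparisons was tested with a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the tags of that comparison, and a tag was called at an adjusted p below 0.05. The words rose and fell refer to such calls. Normalised CPM are counts scaled by library size and TMM factor, given as mean ± SD over 3 cultures. Fold changes are edgeR's log2 estimates ± SE. The gene list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, beside camera with an estimated correlation and fry. Only 1 list was tested per comparison, so its p needed no further adjustment.

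The rule for named tags was fixed before the data were examined. Where no annotation is in hand, it names per comparison the 2 tags with the largest rise and the 2 with the largest fall, among called tags with a mean of 10 CPM or more and no overlap between the groups' libraries. It also names all members of the dioxin list. The 3 longest runs per direction are given by their end tags, and ties in the number of called tags were ordered by the size of the median change. A run is a row of consecutive tag numbers with 5 or more tags called the same way at a fold of 2 or more, with 1 other tag allowed inside. Tag numbers were taken to follow gene order, and a run was described, not tested. Comparisons that share the succinate libraries were set against 50 simulations of unchanged groups. Alternatives were median-of-ratios and total-count scaling, other filters, DESeq2 1.42.0, a fit of 2 groups only, a replicate block, a threshold of 0.01, a test against a fold of 1.5 and leaving out each library. Thinning to the smallest total, library quality weights and leaving out 2 libraries together were added after the data were seen. Figures were drawn with matplotlib 3.10.9.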

Results

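Transcript counts were obtained from 9 cultures of strain RW1, 3 on succinate, 3 on crystalline dibenzo-p-dioxin and 3 on clay-sorbed dibenzo-p-dioxin. Total counts were 375387 ± 168131 (SD, n = 3) on succinate, 400058 ± 52625 (SD, n = 3) on crystalline dioxin and 486849 ± 114434 (SD, n = 3) on clay-sorbed dioxin. The first principal component of log2 CPM, with 56.1% of the variance, separated the succinate cultures from both dioxin groups. The second, with 14.1%, separated the crystalline from the clay-sorbed cultures. Crystalline dioxin replicate 2 lay farthest out on it, at 28.5 against 8.29 and 5.35 for the other two crystalline cultures. No pair of replicates agreed within sampling noise, as 1 library deposited again would (chi-square of 1.64 to 10.8 per degree of freedom). The biological coefficient of variation was 21.3%.

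Transcripts of the dioxin pathway were abundant on all 3 carbon sources. Swit_4897 (dxnA1), which encodes the large subunit of the dioxygenase that opens dioxin degradation, had the highest count in each of the 9 libraries. It took 6.08% ± 1.00 (SD, n = 3) of all counts on succinate, 6.54% ± 1.38 (SD, n = 3) on crystalline dioxin and 6.31% ± 0.39 (SD, n = 3) on clay-sorbed dioxin. The 8 tags of the dioxin list together took 14.3% ± 2.23, 16.1% ± 2.55 and 15.2% ± 0.87 (SD, n = 3 each) of the counts on succinate, crystalline and clay-sorbed dioxin. None of the 3 differences in this share exceeded the spread between cultures (exact permutation tests, two-sided, p = 0.6, 0.8 and 0.8, where 0.1 is the smallest p that 3 against 3 cultures allow). In the authors' deposited RPKM table, Swit_4897 stood at 10569.3 on succinate, 14168.0 on crystalline and 12741.8 on clay-sorbed dioxin.

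**Figure D1:**
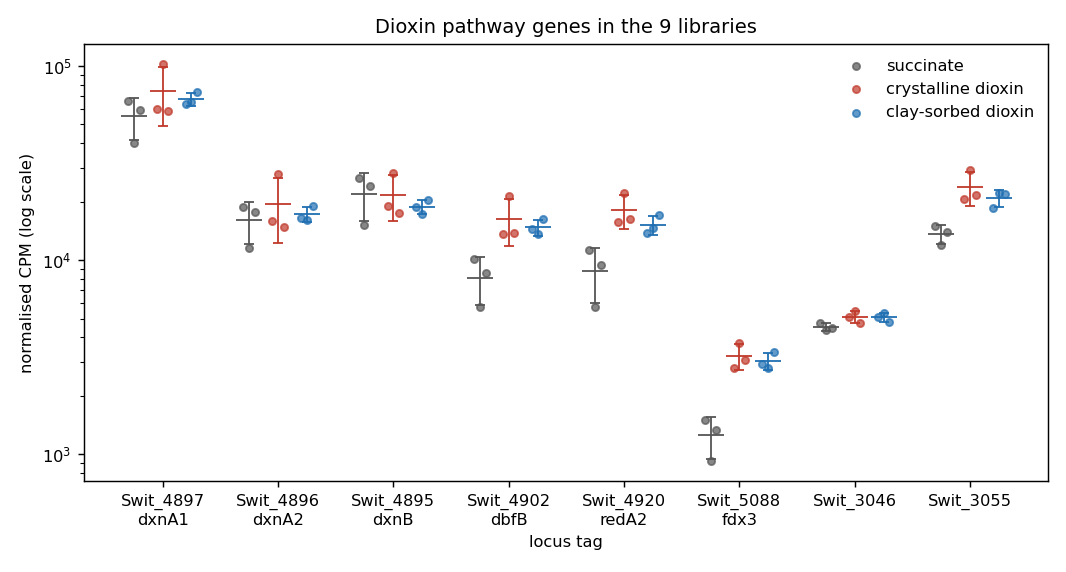
Normalised CPM (log axis) of the 8 dioxin pathway tags in each library, with horizontal bars for group means and error bars for SD (n = 3). Swit_4902, Swit_4920, Swit_5088 and Swit_3055 lie higher in both dioxin groups than on succinate, while Swit_4897, Swit_4896, Swit_4895 and Swit_3046 overlap or differ little.

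The comparison of crystalline dioxin with succinate asks which genes change when dioxin is the carbon source. Dioxin was supplied at 365 µM in both dioxin groups and succinate at 20 mM. The carbon source and its concentration therefore changed together and cannot be told apart against succinate. Within the dioxin list 4 of 8 tags rose, none (0) fell and 4 did not pass the test, and 4 were also called when adjusted over the list alone. DESeq2 called the list 4 higher and 0 lower, and 0 members were lower at an unadjusted edgeR p under 0.05. Swit_5088 (fdx3), a ferredoxin that passes electrons to the dioxygenase, rose most, from 1252 ± 301 to 3204 ± 498 CPM (SD, n = 3), a log2 fold change of 1.35 ± 0.20 (SE; edgeR quasi-likelihood adjusted p = 6.98e-05). Swit_4920 (redA2), the reductase of the same electron chain, rose from 8810 ± 2812 to 18100.0 ± 3631 CPM (log2 fold change 1.04 ± 0.22, adjusted p = 0.0016). Swit_4902 (dbfB), a dioxygenase that cleaves the hydroxylated ring, rose from 8131 ± 2224 to 16285 ± 4415 CPM (1.00 ± 0.22, adjusted p = 0.0020). Swit_3055, a hydrolase acting on the cleaved ring, rose from 13650 ± 1503 to 23799 ± 4691 CPM (0.80 ± 0.18, adjusted p = 0.0022). The subunit genes Swit_4897 and Swit_4896 (dxnA2) had log2 fold changes of 0.42 ± 0.22 and 0.28 ± 0.23 (adjusted p = 0.14 and 0.38). The hydrolase gene Swit_4895 (dxnB) stood at -0.02 ± 0.21 and the ring-cleavage gene Swit_3046 at 0.17 ± 0.16 (adjusted p = 0.95 and 0.45).

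Tested as a list, these tags ranked above the other tags in camera (p = 0.021 at a preset correlation, median log2 fold change 0.61). This call was lost with an estimated correlation (p = 0.40), without crystalline replicate 2 (p = 0.080) and without succinate replicate 2 (p = 0.073). In crystalline replicate 2 the list took 19.1% of counts against 14.7% and 14.6% in the other two crystalline cultures, and in succinate replicate 2 it took 11.8% against 16.1% and 14.97%. These 2 libraries held the highest crystalline and the lowest succinate share, so leaving both out lowers the members' fold changes and narrows the spread. In that fit Swit_4896 and Swit_4895 had log2 fold changes of -0.30 and -0.51 on crystalline dioxin against succinate (edgeR adjusted p = 0.040 and 0.00042). Because of how the libraries were picked, these p-values are no evidence of a fall. With all 9 libraries the values were 0.28 and -0.02. Swit_5088, Swit_4920, Swit_4902 and Swit_3055 kept positive but smaller log2 fold changes without the 2 libraries, at 1.00, 0.59, 0.52 and 0.50. They were called higher there too, but these calls rest on the same narrowed spread and add no support. Under total-count scaling the same 4 rose and 3 of 8 members had negative log2 fold changes, none (0) of them called.

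Beyond the pathway, 610 tags rose and 431 fell on crystalline dioxin among the 3499 tested (edgeR adjusted p below 0.05), of which 464 and 300 changed at least 2-fold. Total-count scaling, which lowers the median log2 fold change of all tags by 0.30, split the calls as 420 higher and 793 lower, so directions here are relative to the TMM-scaled bulk of tags. Swit_0553 rose most, from 25.4 ± 24.6 to 2783 ± 411 CPM (SD, n = 3), a log2 fold change of 6.88 ± 0.37 (SE; edgeR adjusted p = 1.73e-10), which became 7.81 without succinate replicate 2. Swit_5364 followed, from 9.01 ± 3.89 to 723 ± 144 CPM (6.41 ± 0.35, adjusted p = 1.73e-10). Among the falls, Swit_1271 had 47 counts in the succinate libraries and 1 in the crystalline dioxin libraries, a normalised ratio of 41.3 with an exact 95% counting interval of 7.07 to 1667 (edgeR adjusted p = 0.00024). Swit_0068 had 38 counts against 1, a ratio of 33.4 with an interval of 5.65 to 1355 (adjusted p = 0.00065). Both intervals cover counting error only. The single count lay in crystalline replicate 3 for Swit_1271 and in crystalline replicate 1 for Swit_0068, and without that library 0 counts remained. Fitted log2 fold changes without 1 library, which are no bounds, ranged from -6.93 to -4.49 for Swit_1271 and from -6.72 (without crystalline replicate 1) to -4.10 (without crystalline replicate 3) for Swit_0068. Without crystalline replicate 2, 538 tags were called higher and 314 lower, and without succinate replicate 3, 440 and 262.

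Many of these calls sat next to each other. On crystalline dioxin there were 14 runs of neighbouring tags that rose, holding 114 called tags, and 6 runs that fell, holding 34. The longest rising run went from Swit_2179 to Swit_2194, where 15 tags rose with a median log2 fold change of 2.69 and the summed level went from 525 ± 40.8 to 3151 ± 891 CPM (SD, n = 3). The next were Swit_0684 to Swit_0697, with 13 tags and a median of 2.38, and Swit_4539 to Swit_4550, with 11 tags and a median of 2.88. The longest falling runs were Swit_1264 to Swit_1271 (7 tags, median -2.71), Swit_1283 to Swit_1290 (7 tags, median -1.93) and Swit_4865 to Swit_4870 (5 tags, median -2.71), the last being the one with the largest median change among 4 falling runs of 5 called tags. The summed level of Swit_1264 to Swit_1271 was 659 ± 101 CPM on succinate, 107 ± 35.2 CPM on crystalline dioxin and 53.7 ± 6.60 CPM on clay-sorbed dioxin (SD, n = 3 each).

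The comparison of clay-sorbed dioxin with succinate asks the same of dioxin that enters the culture bound to clay. The same 4 dioxin list tags rose: Swit_5088 by a log2 fold change of 1.27 ± 0.20, Swit_4902 by 0.86 ± 0.22, Swit_4920 by 0.78 ± 0.22 and Swit_3055 by 0.61 ± 0.18 (SE; edgeR adjusted p = 0.00013, 0.0060, 0.012 and 0.014). The other 4 did not pass, with log2 fold changes of 0.29 for Swit_4897, 0.11 for Swit_4896, -0.22 for Swit_4895 and 0.16 for Swit_3046, and the count adjusted over the list alone was also 4. The list's camera p was 0.048 at the preset correlation, 0.46 with an estimated correlation, 0.0501 with median-of-ratios scaling, 0.159 without succinate replicate 2, 0.072 without clay-sorbed replicate 3 and 0.051 without crystalline replicate 3, and fry gave a p of 0.057. Under total-count scaling Swit_4895 was lower on clay-sorbed dioxin than on succinate (log2 fold change -0.46, edgeR adjusted p = 0.026). With crystalline and succinate replicate 2 both left out, its log2 fold change was -0.44 (adjusted p = 0.00044). That succinate library held the lowest share of the list on succinate, so the latter p-value is no evidence of a fall. Swit_4920 did not pass without clay-sorbed replicate 3 (adjusted p = 0.059). Swit_3055 did not pass without succinate replicate 3, clay-sorbed replicate 2 or clay-sorbed replicate 3 (adjusted p = 0.063, 0.063 and 0.055).

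In all, 500 tags rose and 446 fell on clay-sorbed dioxin against succinate, 362 and 314 of them at least 2-fold. Total-count scaling, which lowers the median by 0.25, gave 350 higher and 682 lower. Without succinate replicate 3, 350 tags were called higher and 293 lower, and without clay-sorbed replicate 2, 355 and 291. Swit_0553 rose most here too, to 3763 ± 283 CPM (SD, n = 3), a log2 fold change of 7.31 ± 0.38 (SE; edgeR adjusted p = 5.22e-11), or 8.28 without succinate replicate 2, and Swit_0689 rose from 29.7 ± 9.92 to 2852 ± 686 CPM (6.62 ± 0.36, adjusted p = 1.26e-10). Swit_4785 fell from 396 counts in the succinate libraries to 4 in the clay-sorbed dioxin libraries, a normalised ratio of 109 with an exact 95% counting interval of 42.3 to 403 (edgeR adjusted p = 3.91e-07). All 4 counts were in clay-sorbed replicate 1, and the fitted log2 fold change of -6.66 became -9.99 without that library, where 0 counts remained and the fitted value is no bound. It was -6.06 without clay-sorbed replicate 2. Swit_4786 fell from 3523 ± 296 to 56.1 ± 3.91 CPM (-5.96 ± 0.36, adjusted p = 3.96e-10).

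Runs held 92 rising and 79 falling tags on clay-sorbed dioxin. The longest was a falling run of 27 consecutive tags, Swit_1332 to Swit_1358, with a median log2 fold change of -1.69 and a summed level of 13712 ± 1955 CPM on succinate and 4433 ± 140.2 CPM on clay-sorbed dioxin (SD, n = 3). On crystalline dioxin its level was 9116 ± 5905 CPM, and 4 of the 27 tags fell against succinate. Falling runs also covered Swit_1258 to Swit_1271 (13 tags, median -3.42) and Swit_4784 to Swit_4793 (10 tags, median -2.98). The longest rising runs were Swit_0683 to Swit_0697 (15 tags, median 5.63), Swit_2179 to Swit_2191 (12 tags, median 2.36) and Swit_4539 to Swit_4550 (11 tags, median 3.11).

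Of the tags called against succinate, 416 rose and 272 fell in both comparisons, and 6 were called in opposite directions. Independent lists of these sizes would share 87.2 rising and 54.9 falling tags. Because both comparisons use the same succinate libraries, unchanged groups were simulated against them, and in 50 simulations no tag (median 0, highest 0) was called in both. Unchanged groups give almost no calls, so this 0 is no measure of the overlap. Across tags, the log2 fold changes of the 2 comparisons had a correlation of 0.85 and a covariance of 1.00, against 0.50 and 0.073 in the simulations, a difference in covariance of 0.93. The simulated groups also share the succinate libraries, so 0.073 is the covariance that shared controls give under the simulated spread. With 3 succinate libraries the controls could not be split into parts of at least 2. How much the shared controls add to the number of shared calls was therefore not measured, and tags are not independent replicates. Without succinate replicate 3 the shared calls numbered 455 (293 higher, 162 lower), and without clay-sorbed replicate 2 they numbered 500 (319 higher, 181 lower).

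**Figure D2:**
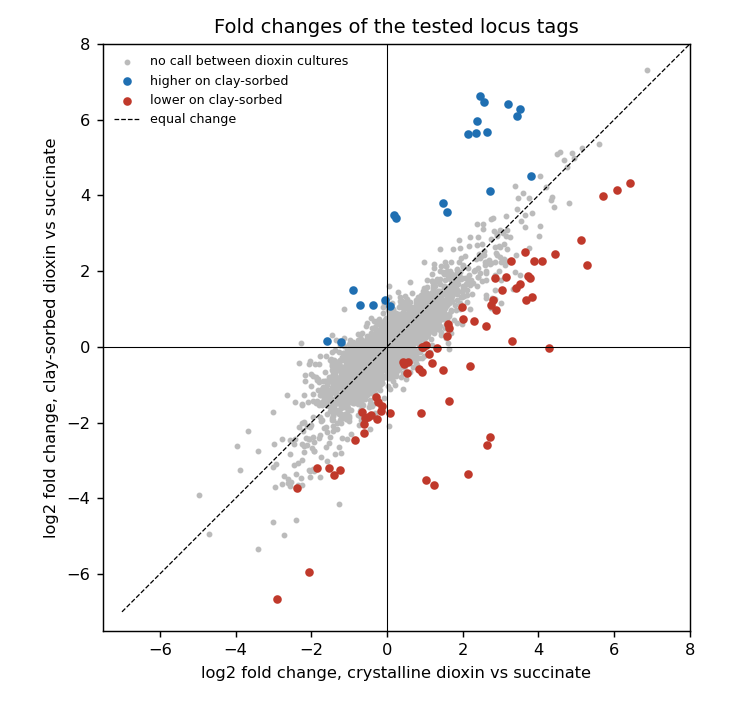
Log2 fold changes against succinate of the 3499 tested tags, crystalline dioxin on the x axis and clay-sorbed dioxin on the y axis, with the dashed line marking equal change. Coloured points are the 22 tags higher and the 72 tags lower on clay-sorbed than on crystalline dioxin, and most other tags lie near the line (correlation across tags 0.85).

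Clay-sorbed and crystalline dioxin were compared at the same nominal dioxin concentration, to ask how sorption to clay changes the response. Here 22 tags were higher and 72 lower on clay-sorbed dioxin (edgeR adjusted p below 0.05), 20 and 64 of them by at least 2-fold. No dioxin list tag (0 of 8) differed, adjusted over all tags or over the list alone, nor at an unadjusted edgeR p under 0.05 or in DESeq2 (0 each), and the list's camera p was 0.38 (0.74 with an estimated correlation). Log2 fold changes of the 8 tags lay between -0.26 and 0.00. The 95% intervals allowed folds from 0.61 (Swit_4920, lower bound) to 1.26 (Swit_5088, upper bound), so smaller differences in either direction remain possible. The list's direction turned from lower to higher when crystalline replicate 2 was left out, where limma's camera gave an adjusted p of 0.48 over the 1 list tested. Cultures with clay but no sorbed dioxin were not analysed here, so the presence of clay and the sorption of dioxin changed together.

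A block of consecutive tags was much higher with clay. All 12 tags from Swit_0683 to Swit_0694 were higher on clay-sorbed than on crystalline dioxin, with a median log2 difference of 3.26, and their summed level was 462 ± 79.4 CPM on succinate, 3165 ± 407 CPM on crystalline and 25281 ± 4307 CPM on clay-sorbed dioxin (SD, n = 3 each). Of these tags, 10 also rose on crystalline dioxin against succinate. Within the block, Swit_0689 was 2852 ± 686 CPM on clay-sorbed and 157 ± 72.1 CPM on crystalline dioxin (log2 difference 4.16 ± 0.30, edgeR adjusted p = 3.24e-08), and Swit_0684 was 1322 ± 245 against 85.8 ± 51.3 CPM (3.90 ± 0.36, adjusted p = 6.17e-07).

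Another block went the other way. All 8 tags from Swit_4785 to Swit_4792 were lower on clay-sorbed than on crystalline dioxin, with a median log2 difference of -4.71. Their summed level was 5619 ± 599 CPM on succinate, 7118 ± 1501 CPM on crystalline dioxin and 249 ± 127 CPM on clay-sorbed dioxin (SD, n = 3 each). The sum hides a mixed block, as on crystalline dioxin against succinate 6 of these tags rose and 2 fell. Those that fell were Swit_4785, from 321 ± 74.0 to 39.9 ± 33.6 CPM, and Swit_4786, from 3523 ± 296 to 836 ± 458 CPM. Swit_4791 fell most, from 1061 ± 388 CPM on crystalline to 21.3 ± 18.3 CPM on clay-sorbed dioxin (-5.49 ± 0.41, edgeR adjusted p = 3.40e-08), followed by Swit_4790 from 2161 ± 917 to 52.9 ± 54.04 CPM (-5.23 ± 0.48, adjusted p = 6.05e-07). Without clay-sorbed replicate 1, which held 23 and 62 of their counts in that group, the log2 differences were -6.42 and -6.37. A shorter block, Swit_5364 to Swit_5368, was lower on clay-sorbed dioxin in all 5 tags (median -1.93), with summed levels of 38.3 ± 0.72, 1769 ± 431 and 443 ± 86.7 CPM on succinate, crystalline and clay-sorbed dioxin. In this block 3 tags were called at a fold of 2 when crystalline replicate 1 or clay-sorbed replicate 2 was left out.

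**Figure D3:**
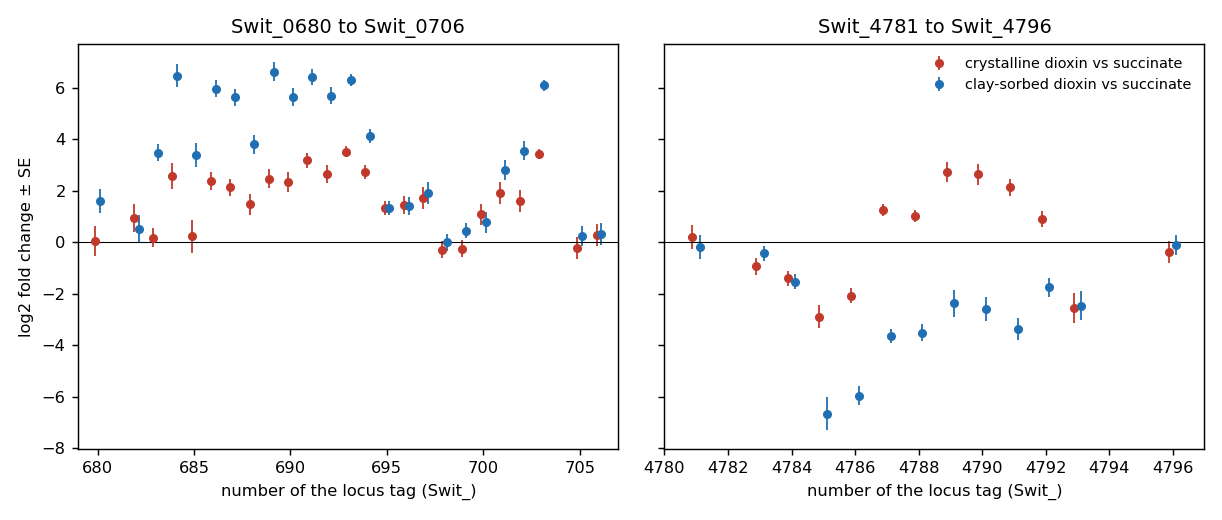
Log2 fold changes against succinate (points, with SE bars) along consecutive locus tags for crystalline and clay-sorbed dioxin. From Swit_0683 to Swit_0694 the clay-sorbed values lie above the crystalline ones, and from Swit_4787 to Swit_4792 they lie below 0 while the crystalline values lie above 0.

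Of the 72 tags lower on clay-sorbed than on crystalline dioxin, 47 had risen on crystalline dioxin against succinate, and 20 of these also rose on clay-sorbed dioxin. On clay-sorbed dioxin 26 of the 72 fell below succinate, of which 6 had risen on crystalline dioxin, 8 had fallen and 12 were not called there. Of the 22 tags that were higher, 20 had risen on clay-sorbed dioxin against succinate and 13 had risen in both. These comparisons share libraries with the one that chose the tags, which favours such rises and falls, and no value for unchanged tags was computed. The count of 94 calls changed with the libraries in the fit. It was 167 (45 higher, 122 lower) without crystalline replicate 2 and 129 (36 higher, 93 lower) without crystalline replicate 3. It was 48 without clay-sorbed replicate 1, replicate 2 or replicate 3 in turn, so this drop does not point to a particular clay-sorbed library. These 48 were 17 higher and 31 lower without replicate 1, and 18 higher and 30 lower without replicate 2 or replicate 3. The count was 59, with 20 higher and 39 lower, when the succinate libraries were left out of the fit.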

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

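The test that leaves out crystalline replicate 2 for the balance of calls was chosen after its result was seen, and thinning was added after the data were examined; the other tests below were set before their results.

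Swit_4787 to Swit_4792 stood out because they moved in opposite directions against succinate in the 2 dioxin cultures and the difference itself was called. Between clay-sorbed and crystalline dioxin their log2 differences were -4.89 for Swit_4787, -4.53 for Swit_4788, -5.09 for Swit_4789, -5.23 for Swit_4790, -5.49 for Swit_4791 and -2.66 for Swit_4792. A single library would have to carry the pattern, yet all 6 tags kept both signs in each of the 9 fits without 1 library. After thinning every library to the smallest total, 6 of 6 kept both signs and the call. Thinning keeps each tag's share of its library on average, so it could hardly turn such changes. Under total-count scaling 6 of 6 kept both signs. That scaling moved the median log2 fold changes against succinate by only -0.30 and -0.25. The smallest changes of the 6 tags were 0.90 on crystalline and -1.76 on clay-sorbed dioxin, so no sign could turn. The thinning and scaling tests could therefore not decide. Depth and scaling act on all tags of a library alike. Between the dioxin cultures, however, the median log2 difference of all tested tags was only -0.040, or 0.0094 under total-count scaling. The differences of -2.66 to -5.49 argue against depth and scaling as the cause for these 6 tags. A response to clay, to sorbed dioxin or to a slower supply of substrate may each account for the pattern, and none of these was tested because clay and sorption changed together.

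More tags were lower (72) than higher (22) on clay-sorbed than on crystalline dioxin. The split depended on the libraries, with 31 lower and 17 higher without clay-sorbed replicate 1, and 30 lower and 18 higher without replicate 2 or replicate 3 of that group. Scaling stays open: at least 72.4% of calls were lower under total-count and median-of-ratios scaling, but these moved the median log2 difference by only 0.045 and 0.010, too little to test it. Crystalline replicate 2 and large clusters are argued against as the whole cause, with 73.1% of calls lower without that library and 81.0% of regions lower (34 against 8) when called tags within 10 tag numbers were counted once. No biological explanation was tested.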

How the results depend on the processing

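Thinning, library quality weights and leaving out 2 libraries together were chosen after seeing the data. Across alternatives, 50 counts of calls stayed within 1.5 times the reported count and 13 did not. The test against a fold of 1.5 gave 496, 490 and 46 calls for crystalline against succinate, clay-sorbed against succinate and clay-sorbed against crystalline dioxin, and a threshold of 0.01 gave 585, 570 and 48. Library quality weights gave 1493 for clay-sorbed against succinate. For clay-sorbed against crystalline dioxin, the fit of 2 groups only gave 59 and leaving out crystalline and succinate replicate 2 together gave 220, of which 88 were among the 94. Leaving out 1 library gave 702 to 1322, 643 to 1187 and 48 to 167 calls, and 455 (without succinate replicate 3) to 899 shared calls. The dioxin list's p ranged from 0.0081 to 0.080, 0.016 to 0.159 and 0.163 to 0.588 without 1 library, and in the last comparison its direction turned without crystalline replicate 2 (0.485). With an estimated correlation it was 0.395 and 0.463 against succinate. For clay-sorbed dioxin against succinate it was also above 0.05 with fry (0.057) and median-of-ratios scaling (0.0501). The replicate numbers gave no sign of pairing the cultures (same-numbered deviations correlated between -0.10 and 0.11, and 4 of 18 best matches had the same number). The replicate block gave 944, 862 and 80 calls, and a list p of 0.061 for clay-sorbed dioxin against succinate.

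Among named tags, sign changes occurred only in dioxin list tags that had not been called. For crystalline dioxin against succinate, Swit_4896 had -0.052 and Swit_3046 -0.15 under total-count scaling, and without replicate 2 of both groups Swit_4897 had -0.11 and Swit_4896 -0.30. Without 1 library Swit_4896 ranged from -0.057 to 0.44 and Swit_4895 from -0.27 to 0.14. For clay-sorbed dioxin against succinate, total-count scaling gave -0.14 for Swit_4896 and -0.097 for Swit_3046. Without replicate 2 of both groups Swit_4896 had -0.093, and without 1 library it ranged from -0.093 to 0.28. Between the dioxin cultures, leaving out replicate 2 of both groups turned Swit_4897 to 0.21, Swit_4896 to 0.20, Swit_4895 to 0.069, Swit_4902 to 0.14, Swit_5088 to 0.074, Swit_3046 to 0.080 and Swit_3055 to 0.016. Without 1 library the ranges were -0.27 to 0.22, -0.33 to 0.21, -0.32 to 0.077, -0.25 to 0.15, -0.17 to 0.084, -0.043 to 0.087 and -0.28 to 0.025 in the same order. Swit_3046, at -0.0046, also became 0.0026 with median-of-ratios scaling, 0.051 with total-count scaling, 0.0094 with no filter, 0.017 with the 10 CPM filter, 0.020 with 2 groups only, 0.0088 after thinning and 0.020 with quality weights, and Swit_4897 became 0.012 with quality weights. The causes were not tested. In the run Swit_4865 to Swit_4870 only 2 tags passed the count filter after thinning, and in Swit_4539 to Swit_4550 only 7 with 2 groups, and every tag tested there was called. Tests on RPKM per library, without ribosomal and transfer RNA genes, and of replicon shares were not run, because the RPKM table has 1 value per group and no annotation was in hand. Thinning every library to the smallest total gave 889, 844 and 76 calls. Simulated 2-fold changes were recovered in 44.9% to 45.8% of cases, at 1 depth, which does not separate depth from the number of replicates and their spread.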

Other observations

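Swit_4894, next to the dioxygenase genes, ranked 2 in abundance, with 40235 ± 10939 CPM on succinate, 35474 ± 10348 CPM on crystalline and 37435 ± 3611 CPM on clay-sorbed dioxin (SD, n = 3 each), and was not called in any of the 3 comparisons. Swit_4004 (26309 ± 2164 CPM on succinate) ranked 3 and was not called either. Swit_3048 ranked 4, with 19233 ± 324 CPM on succinate, 24682 ± 4899 CPM on crystalline and 24795 ± 1681 CPM on clay-sorbed dioxin (log2 fold changes 0.36 ± 0.17 and 0.37 ± 0.17, edgeR adjusted p = 0.11 for both), and was not called. Swit_3144, with rank 8, rose on crystalline dioxin from 10394 ± 797 to 21038 ± 9936 CPM (log2 fold change 1.02 ± 0.24, edgeR adjusted p = 0.0033), with 13722 ± 756 CPM on clay-sorbed dioxin. Ranks are by mean CPM over all 9 libraries, and the order within a group can differ. CPM are not corrected for gene length, so these ranks are of read counts and the order by RPKM can differ. These tags were chosen for their abundance after the data were seen.

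The test of neighbouring tags was chosen after the runs were seen, and that of the surroundings of the dioxin genes before its result. The log2 fold changes of consecutive tags correlated (Spearman, across 2797 pairs of tags) at 0.50, 0.55 and 0.31 for crystalline against succinate, clay-sorbed against succinate and clay-sorbed against crystalline dioxin, above the highest of 1000 shuffled orders (0.069 at most). This is consistent with neighbouring genes being transcribed together, although pairs of tags are not independent. The 64 tested tags within 10 tag numbers of a dioxin list member, members left out, included 17 that rose and 6 that fell on crystalline dioxin. Among all 3499 tested tags, 610 rose and 431 fell. Camera gave p = 0.023 for these 64 tags, or 0.41 with an estimated correlation. The estimated correlation between these tags was 0.155, against the preset 0.01 behind the smaller p. That p therefore gives no firm support to the hypothesis that the surroundings rise with the pathway.

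Chance in the grouping could not be assessed at a share under 0.05, since 6 libraries allow 10 splits. The real splits gave 1041, 946 and 94 calls, the most in each case (1 of 10 splits), and the highest of the others gave 0 in each comparison. Every other split mixes both conditions within a group, so real differences between them enter the spread, and this 0 is no chance level.

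Ratios of the authors' deposited RPKM exceeded the ratios of plain count shares by a median log2 of 0.29 for crystalline dioxin against succinate and 0.23 for clay-sorbed dioxin against succinate, with an SD of 0.033 and 0.014 over 625 tags with RPKM above 50. The TMM factors moved the medians by 0.30 and 0.25 in the same direction. Swit_2411 was listed in the RPKM table alone, at 234.9 on succinate, 149.2 on crystalline and 168.7 on clay-sorbed dioxin, and Swit_5400 in the count table alone, with 8 to 21 counts per library.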
